A study of Mus musculus with 9 samples.

How the data were processed

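Messenger RNA was measured by sequencing in 9 mouse liver samples in 3 groups of 3: control, D-gal/LPS, and WZB given before D-gal/LPS. Per the labels, the livers came from male C57BL/6 mice aged 6 to 8 weeks. Total RNA was checked for integrity and treated with DNase before mRNA was isolated for Illumina libraries. In this model of acute liver injury the letters D-gal and LPS usually stand for D-galactosamine and lipopolysaccharide. The letters WZB are not expanded in the labels, and the design text of the series speaks of GLUT1 inhibitors given as pretreatment. Doses, times and any injury score are not given in the sources used here. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples.

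The authors deposited 1 table with a read count and an FPKM value (fragments scaled by gene length and depth) for each gene and library. The deposited counts were whole numbers and were used for every test. The deposited FPKM values were used for 1 alternative only. Per the submitters' processing notes, the reference was GRCm38.p4 (mm10), and R 4.1.2 and limma were among the tools. The aligner, the counting program, the annotation release and the strandedness of the libraries are not given in the sources used here. Gene positions are 1-based on that build, as in the deposited table. Of 21 value columns in the table, 3 matched no labelled sample and were not analysed here.

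The table was checked before any test. It held 34745 genes, of which 14740 had a count of 0 in all 9 libraries. Counts and FPKM values were proportional in all of the 18345 genes that could be compared, within a tolerance of 0.01. Of the gene identifiers, 98.62% were found in the reference annotation used here, and 99.94% of those overlapped its position, while 80.83% had the same start and end. A gene symbol stood on more than 1 identifier in 59 cases. No 2 libraries were identical. Pearson correlations between libraries of a group lay between 0.9799 and 0.9868, and the chi-square per gene lay between 12.93 and 29.42, so the replicates differed by more than counting noise.

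Gene tests used edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr on the groups, which left 13583 genes holding 99.93% of the reads and removed 21162. Libraries were scaled by TMM factors. All 9 libraries entered 1 quasi-likelihood fit of 3 groups with robust estimation, no block and 6 residual degrees of freedom. The adjusted p values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. The 3 comparisons were D-gal/LPS against control, WZB with D-gal/LPS against D-gal/LPS, and WZB with D-gal/LPS against control. Levels are CPM, counts scaled to a common library size, as mean ± SD of 3 libraries. Log2 fold changes are given ± an approximate standard error. It is the size of the fold change divided by the square root of its quasi-likelihood F statistic. Where all control counts were 0, a lower bound of the fold was computed by placing 3 counts over the whole control group.

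Gene groups were 38 lists of 562 distinct genes. They held glucose transporters, pathways of liver metabolism, inflammatory and stress genes, and markers of neutrophils, monocytes, Kupffer cells, macrophages, lymphocytes, endothelium, stellate cells, cholangiocytes and red blood cells. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, which compares its genes with all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test was run with a correlation estimated for each list. The fry test of limma was run beside it. Its p value asks whether the genes move on balance one way, its mixed p value asks for change in either direction, and neither compares the list with other genes. Gsdme was matched as Dfna5, Itgam was matched by its identifier, and Hbb-b1 and Hbb-b2 were not found.

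The groups, the tests, the lists and the rule for named genes were chosen before the data were examined. The rule took Slc2a1, Slc2a2 and Slc2a3 first. For each of the first 2 comparisons it took the 6 largest rises and 6 largest falls. These were sought among genes that passed the test with no overlap between the groups' samples, a mean of at least 5 CPM, and no predicted gene or clone name. It added the 3 members of each list with the smallest adjusted p, then Tnf, Il1b, Il6, Ccl2, Alb and Cyp7a1. Last came the 6 genes that moved in opposite directions in both comparisons with the smallest larger adjusted p. This gave 195 genes, of which a part is printed, so that some of the largest changes are not named.

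Alternatives chosen before the data were examined were a block on the replicate number, fits of only the 2 groups compared, and DESeq2 size factors or upper quartile factors. Others were no filter, a filter of 5 CPM in 3 samples, DESeq2 1.42.0, voom with sample weights, a log2 fold change of at least 1, and leaving out each library. A change of the FPKM pseudocount was also planned and was not run, since counts were used. Total-count scaling, removal of mitochondrial and globin genes, limma on log2(FPKM + 1), and a split of the D-gal/LPS libraries between the first 2 comparisons were added after the data had been seen. The split kept the filter and the TMM factors and fitted 4 groups with 5 residual degrees of freedom.

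Depth was 15072509 to 18106895 counted reads per library. The test was tried on simulated data of 13583 genes with the depth and spread of these libraries. In the comparison of D-gal/LPS with control it called 16.4% of 67 genes changed 1.5-fold, 53.7% of 67 changed 2-fold and 87.9% of 66 changed 4-fold. In the comparison of WZB with D-gal/LPS alone these shares were 20.9%, 64.2% and 87.9%. Every simulated gene that was called had the right direction, and 3 unchanged genes were called in each comparison (2.8% and 2.5% of calls). Few simulated genes were changed, whereas the real comparisons called 58.4% and 28.5% of genes. The adjusted threshold was therefore stricter in the simulations, and their shares are not those of the real tests.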

Results

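Liver transcripts were compared between control mice, mice given D-gal/LPS, and mice given WZB before D-gal/LPS, with 3 libraries a group. The glucose transporter genes come first, since the design text of the series speaks of GLUT1 inhibitors. The injury itself, the effect of WZB on injured livers, and what still differed from control livers follow.

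Slc2a1, the gene of GLUT1, rose from 8.02 ± 1.36 CPM in control livers to 41.8 ± 4.87 CPM after D-gal/LPS, and stood at 19.1 ± 2.46 CPM with WZB (n = 3 each). The log2 fold change was 2.38 ± 0.15 with injury (edgeR adjusted p = 1.89e-08), and -1.13 ± 0.15 with WZB (edgeR adjusted p = 0.000109). Slc2a1 had 107, 136 and 178 counts in the control libraries, 630, 655 and 777 after D-gal/LPS, and 271, 221 and 351 with WZB. Slc2a3, the gene of GLUT3, a transporter of neurons and blood cells, rose from 0.200 ± 0.131 to 5.24 ± 0.486 CPM and was at 2.10 ± 0.161 CPM with WZB. Its counts were 4, 5 and 1 in control libraries, 85, 88 and 85 after D-gal/LPS, and 29, 26 and 37 with WZB. Its log2 fold changes were 4.70 ± 0.39 (edgeR adjusted p = 2.36e-07) and -1.32 ± 0.29 (edgeR adjusted p = 0.00397). Slc2a2, the gene of GLUT2, the main glucose transporter of hepatocytes, had 158 ± 37.8 CPM in control livers and 169 ± 10.8 CPM after D-gal/LPS (edgeR adjusted p = 0.665). With WZB, Slc2a2 rose to 276 ± 49.0 CPM (log2 fold change 0.71 ± 0.19, edgeR adjusted p = 0.0238). That call was lost with total-count scaling (adjusted p = 0.0881) and in 5 of the 9 fits that left out 1 library (adjusted p = 0.0514 to 0.131). The libraries held 3002, 1894 and 3329 counts of Slc2a2 in controls, 2908, 2417 and 3063 after D-gal/LPS, and 4203, 2927 and 5071 with WZB. Slc2a1 lies at chromosome 4:119108711-119137983, Slc2a2 at 3:28697903-28731359 and Slc2a3 at 6:122727809-122801640 (GRCm38). Of 7 measured glucose transporters, Slc2a1, Slc2a3 and Slc2a6 rose with injury and none fell (median log2 fold change 0.10, or 0.05 with total-count scaling, camera adjusted p = 0.0316). For that list the adjusted p = 0.109 with an estimated correlation. With WZB, Slc2a1, Slc2a3 and Slc2a6 fell while Slc2a2, Slc2a8 and Slc2a9 rose, and the list as a whole had a median of -0.38 (camera adjusted p = 0.343).

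**Figure D1:**
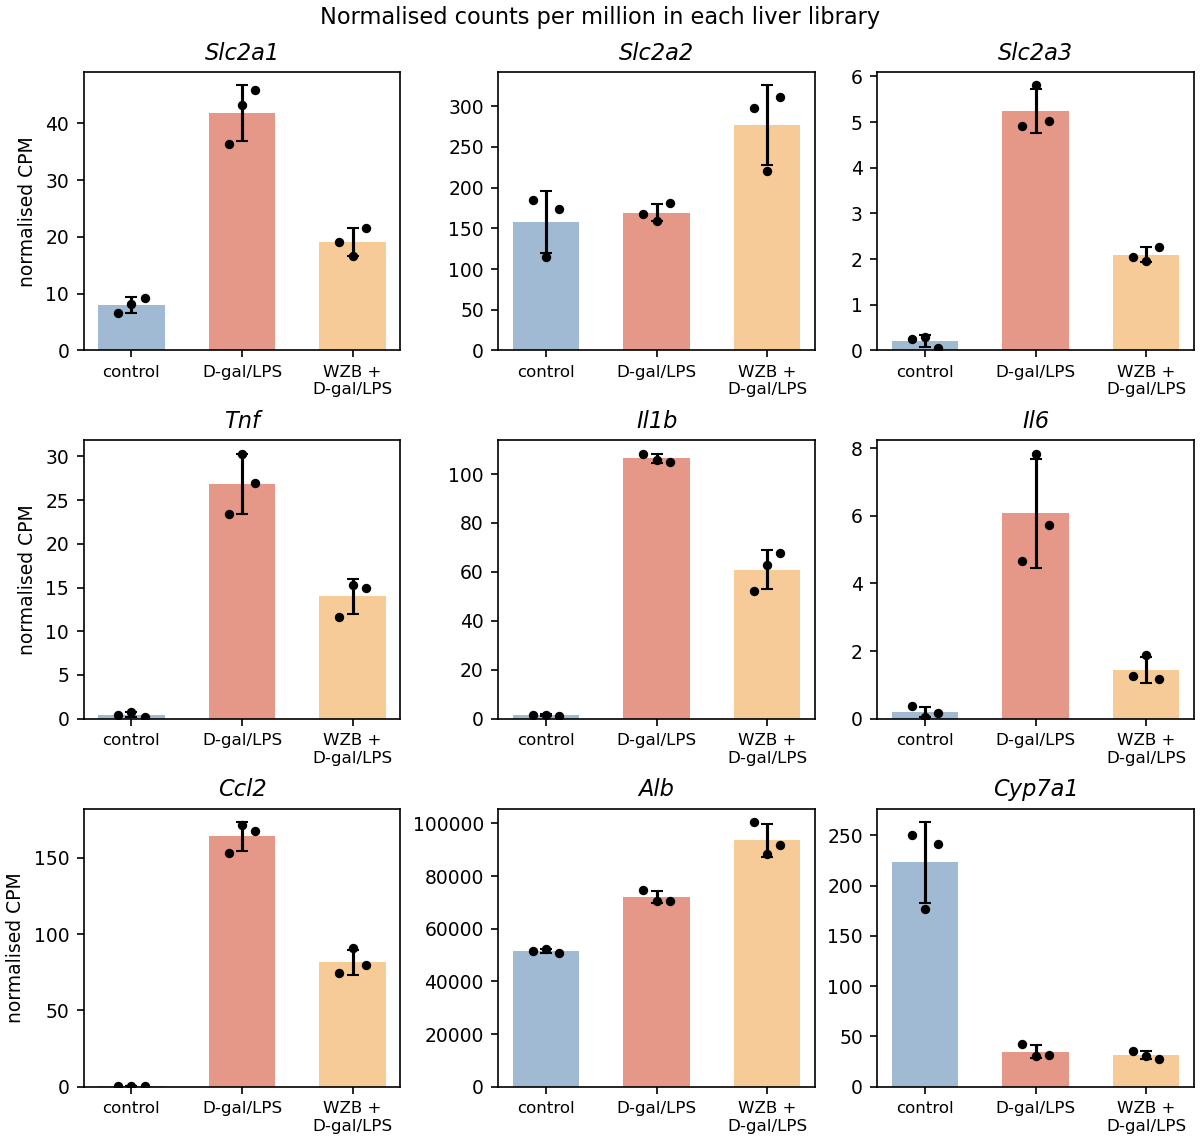
Levels of 9 genes in every library, in CPM, where bars show mean ± SD of 3 libraries and points show libraries. The genes are 3 glucose transporters, 4 inflammatory genes, and Alb and Cyp7a1 of hepatocytes.

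D-gal/LPS raised inflammatory genes by large factors and lowered transcripts of hepatocyte regulators. Ccl2, which draws monocytes, rose from 0.652 ± 0.0426 to 164 ± 9.57 CPM (log2 fold change 7.95 ± 0.14, edgeR adjusted p = 3.54e-13, n = 3). Tnf, the gene of tumour necrosis factor, rose by 6.02 ± 0.30, Il1b by 6.29 ± 0.18 and Il6 by 4.92 ± 0.44 log2 units. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 223 ± 40.2 to 35.0 ± 6.77 CPM (log2 fold change -2.67 ± 0.17, edgeR adjusted p = 3.41e-07). Alb, the gene of serum albumin, rose slightly, from 51530 ± 650 to 71910 ± 2293 CPM (0.48 ± 0.07). Of 13583 genes tested, 3957 rose and 3974 fell in D-gal/LPS livers, 58.4% of all. At least 2-fold changes were found for 2454 of the higher and 1731 of the lower genes. The samples of the groups did not overlap for 65.5% of genes, where 10% is the share by chance.

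Among the large rises were genes without any control counts. Ch25h, which makes 25-hydroxycholesterol in activated macrophages, was at least 773-fold higher. Csf3, the growth factor of neutrophils, was at least 314-fold higher, Fgf23, a hormone of phosphate balance, at least 236-fold, and Tnip3, which restrains NF-kB signalling, at least 227-fold. Slfn4, an interferon-responsive gene of myeloid cells, rose by 9.75 ± 0.29 log2 units to 884 ± 27.1 CPM. Among the large falls were those of Mfsd2a, a lysolipid transporter of fasting liver (-6.14 ± 0.65), Hdhd3 (-4.98 ± 0.36) and Usp2, a deubiquitinase under clock control (-4.92 ± 0.24). Next came Inhbe, a liver activin subunit (-4.33 ± 0.17), Alas1, the rate-limiting enzyme of liver haem synthesis (-3.86 ± 0.21), and B3galt1, a galactosyltransferase (-3.64 ± 0.26).

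Genes of inflammatory signalling rose as groups. In this comparison the count adjusted over the list alone equals the count over all genes unless a second count is given. Exceptions to a list's direction that are named below without a value were chosen after their values were seen. All 14 measured cytokines rose (median log2 fold change 6.16, or 5.49 with 4 genes at their bound, camera adjusted p = 2.87e-18). Of 18 chemokines 17 rose, and 18 adjusted over the list alone, with a median of 5.00, or 4.77 at the bound (camera adjusted p = 7.54e-24). Ccl3 rose by 7.18 ± 0.18 and Ccl4, a related chemokine, by 6.45 ± 0.20. Of 20 interferon-stimulated genes 17 rose and none fell, and 19 rose adjusted over the list alone (median 3.37, camera adjusted p = 1.88e-25). Examples were Cmpk2 (4.50 ± 0.12), the guanylate-binding gene Gbp3 (4.40 ± 0.12) and the antiviral Ifit3 (4.01 ± 0.11). Of 19 NF-kB targets 17 rose while Nfkbib and Bcl3 fell (median 2.27, camera adjusted p = 1.21e-16). The endothelial adhesion genes Sele (7.29 ± 0.24) and Vcam1 (5.12 ± 0.15) were among them, as was Tnip1, which restrains NF-kB signalling (3.24 ± 0.11). Of 19 immediate early genes 18 rose and Jund fell (median 3.6, camera adjusted p = 1.36e-16), with Fosl2 at 3.6 ± 0.11 and Klf6 at 3.92 ± 0.15. Of 12 inflammasome genes 10 rose and none fell (median 2.33, camera adjusted p = 5.28e-06). Casp4, the sensor of intracellular LPS, rose by 4.24 ± 0.14 and Casp1, which processes IL-1, by 3.13 ± 0.19. Of 11 genes of coagulation and fibrinolysis 10 rose (median 2.03, camera adjusted p = 2.49e-11). These included Thbs1, a matrix glycoprotein of platelets (8.98 ± 0.21), and Plaur, the urokinase receptor (6.25 ± 0.20).

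Markers of other cell types rose in the same livers. All 13 neutrophil markers rose (median 6.57, or 6.19 at the bound, camera adjusted p = 7.21e-28), with S100a9, an abundant neutrophil protein, going from 1.42 ± 0.188 to 103 ± 18.2 CPM. All 12 monocyte markers rose (median 4.61, camera adjusted p = 9.63e-21), among them Cd14, a co-receptor of LPS (4.57 ± 0.16). Of 14 stellate cell and fibroblast markers 13 rose (median 2.72, camera adjusted p = 1.47e-14), among them the matrix genes Dcn (3.46 ± 0.09) and Reln (3.55 ± 0.12). Of 13 macrophage markers 12 rose (median 2.06, camera adjusted p = 5.03e-09, and adjusted p = 0.0757 with an estimated correlation). Of 14 sinusoidal endothelial markers 13 rose and Kdr fell (median 1.47, camera adjusted p = 4.58e-08, and adjusted p = 0.0732 with an estimated correlation). Lyve1, a hyaluronan receptor of that endothelium, rose by 5.33 ± 0.15 and the junction gene Cdh5 by 4.03 ± 0.13. Of 12 Kupffer cell markers 9 rose, Clec4f by 1.37 ± 0.12, while the iron exporter Slc40a1 (-1.51 ± 0.13) and Kcna2 fell. The median was 1.26 (camera adjusted p = 0.0317, and adjusted p = 0.373 with an estimated correlation). Of 13 T, NK and B cell markers 8 rose, and 10 adjusted over the list alone (median 1.56, camera adjusted p = 0.00215, and adjusted p = 0.101 with an estimated correlation). Gzmb, a protease of killer cells, rose by 5.79 ± 0.19. All 8 red blood cell transcripts rose (median 5.81, or 5.78 at the bound, camera adjusted p = 4.83e-09, and adjusted p = 0.0586 with an estimated correlation). The globin genes among them may share reads between close paralogs, so they may not count as separate genes. Globin genes took 0.0068 ± 0.0015% of reads in control livers and 0.3805 ± 0.0546% after D-gal/LPS. Of 8 cholangiocyte markers 6 rose and 1 fell, with a median of 1.47 (camera adjusted p = 0.138).

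**Figure D2:**
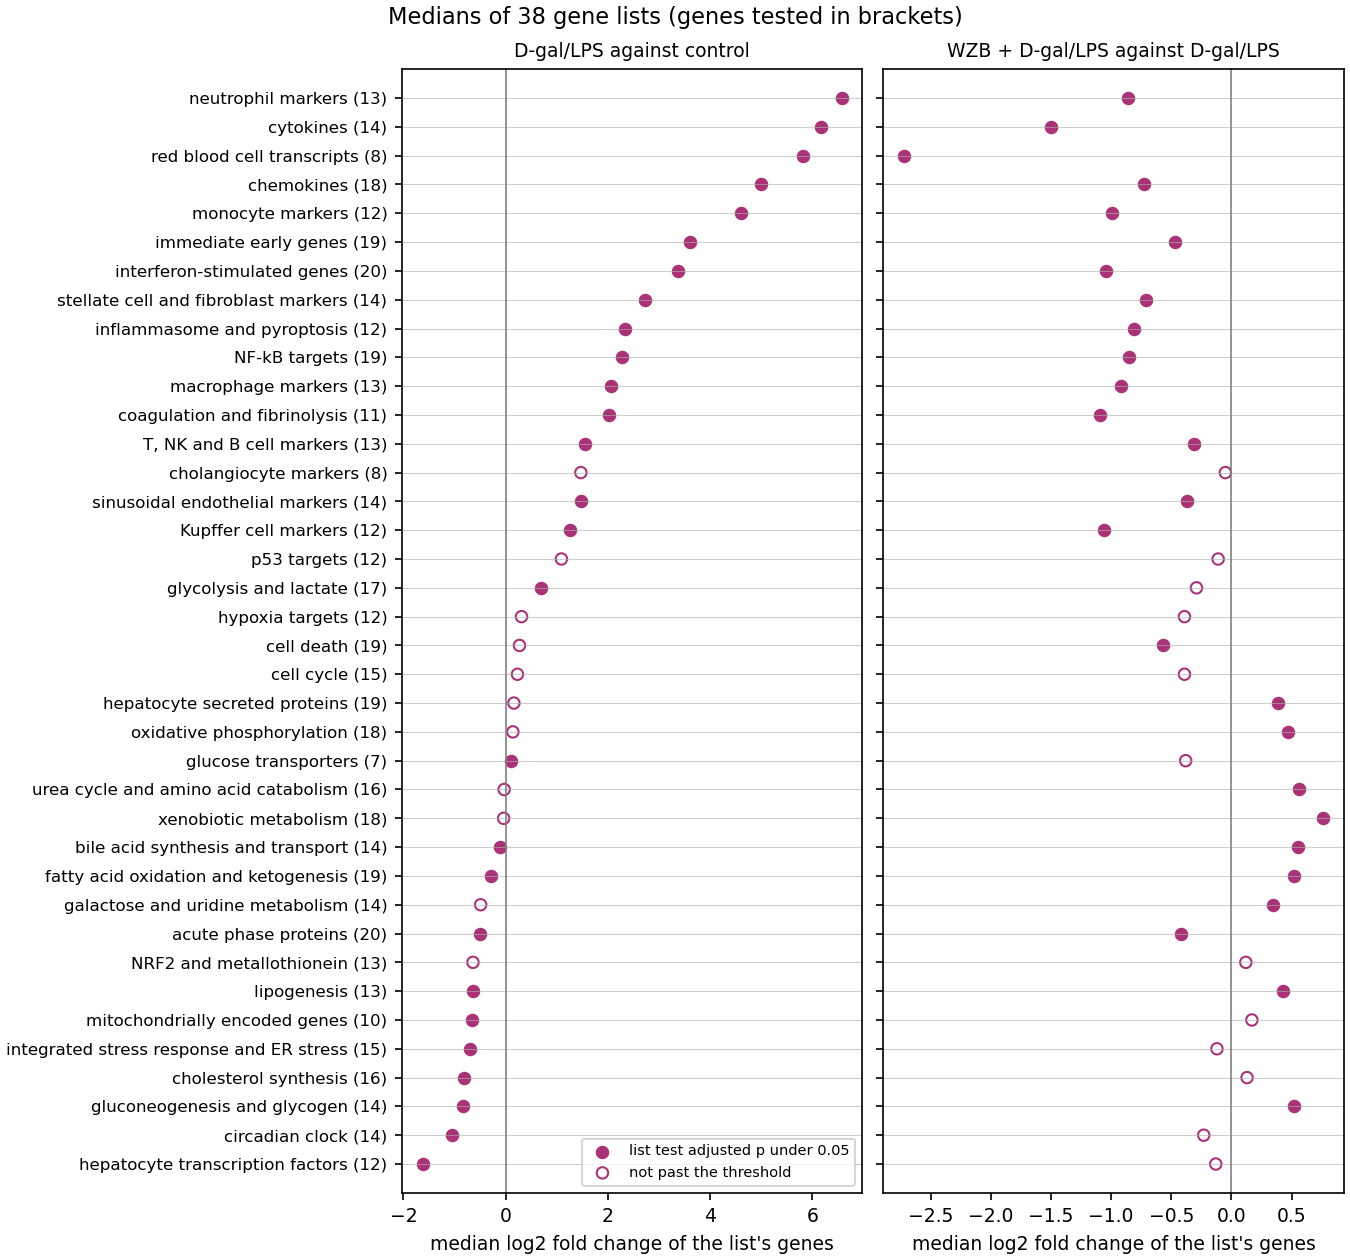
Median log2 fold change of the 38 gene lists, with D-gal/LPS against control on the left and WZB with D-gal/LPS against D-gal/LPS on the right. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation.

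Hepatocyte genes did not move alike in these livers, in which the neutrophil marker median stood at 6.57 and the monocyte median at 4.61. Of 12 hepatocyte transcription factors 11 fell and none rose (median -1.62, camera adjusted p = 4.64e-07). Cebpa, a regulator of hepatocyte differentiation, fell by 2.92 ± 0.14 log2 units, Foxa3 by 2.71 ± 0.16 and Rxra, a partner of many nuclear receptors, by 1.83 ± 0.09. Of 19 secreted hepatocyte proteins Alb, Trf, F2, F9 and Serpind1 rose and Fetub, F7 and Proc fell, with a list median of 0.16 (camera adjusted p = 0.812). Of 14 genes of gluconeogenesis and glycogen 10 fell while Fbp1 and Pygl rose (median -0.84, camera adjusted p = 0.00352). G6pc, which releases free glucose, fell from 233 ± 38.9 to 37.5 ± 4.54 CPM. Of 17 glycolysis genes 12 rose while Ldha and Pdk1 fell (median 0.70, camera adjusted p = 8.34e-07, and adjusted p = 0.0586 with an estimated correlation). Hk2 (5.19 ± 0.20), Hk1 (4.19 ± 0.18) and Pkm (4.1 ± 0.12), isoforms found outside resting hepatocytes, rose most clearly.

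Genes of lipid metabolism fell more often than they rose, and bile acid genes went both ways. Of 13 lipogenesis genes 9 fell and none rose (median -0.64, camera adjusted p = 0.0104, and adjusted p = 0.403 with an estimated correlation). Acaca, the acetyl-CoA carboxylase gene, fell by 1.40 ± 0.13 and Thrsp, a lipogenic gene under thyroid hormone control, by 0.84 ± 0.10. Of 16 cholesterol genes 11 fell and none rose (median -0.82, camera adjusted p = 0.0018, and adjusted p = 0.414 with an estimated correlation), with Insig1, which restrains sterol synthesis, at -1.52 ± 0.10. Of 19 genes of fatty acid oxidation and ketogenesis 10 fell and 2 rose, Pdk4 among them (median -0.29, camera adjusted p = 0.0317, and adjusted p = 0.426 with an estimated correlation). Ppara, their main regulator, fell by 1.38 ± 0.16. Of 14 bile acid genes 6 rose and 6 fell, and 7 fell adjusted over the list alone (median -0.11, camera adjusted p = 0.0422, and adjusted p = 0.444 with an estimated correlation). Nr1h4, the bile acid receptor FXR, fell by 2.41 ± 0.16. Of 18 xenobiotic genes Cyp2c29, Cyp2f2 and Ugt2b1 rose and Cyp2a5, Por, Fmo5, Nr1i2 and Nr1i3 fell (median -0.04, camera adjusted p = 0.347). Of 16 genes of the urea cycle and amino acid catabolism 3 rose, Cps1 and Otc among them, and Asl, Arg1, Nags, Tat and Prodh fell (median -0.03, camera adjusted p = 0.132), and the call of Otc was lost with upper quartile factors (adjusted p = 0.0947). Nags, which makes the activator of the urea cycle, fell by 3.39 ± 0.14. Of 18 genes of oxidative phosphorylation 8 rose and none fell (median 0.14, camera adjusted p = 0.548). Of 10 mitochondrially encoded genes 8 fell, and 9 adjusted over the list alone, while mt-Co1 rose. The median was -0.65 (camera adjusted p = 0.0146, and adjusted p = 0.427 with an estimated correlation). Mitochondrial genes took 19.1 ± 1.64% of reads in control livers and 15.1 ± 0.41% after D-gal/LPS. Of 14 genes of galactose and uridine metabolism 7 fell while Ugp2 and Upp1 rose (median -0.49, camera adjusted p = 0.0865). Upp1, which degrades uridine, rose by 3.84 ± 0.17 and Cda, the cytidine deaminase, fell by 3.22 ± 0.27.

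Acute phase and stress genes moved in several directions. Of 20 acute phase genes 12 fell and Cp rose (median -0.50, camera adjusted p = 0.00168, and adjusted p = 0.403 with an estimated correlation), with the protease inhibitor Serpina3n at -1.57 ± 0.08. Of 15 genes of the integrated stress response and ER stress 10 fell and Ppp1r15a rose (median -0.70, camera adjusted p = 0.00115). Xbp1, a transcription factor of the ER stress response, fell by 1.81 ± 0.12. Of 14 clock genes 10 fell, Dbp by 3.26 ± 0.14 and Per3 by 2.09 ± 0.11, while Arntl, Clock and Cry1 rose (median -1.05, camera adjusted p = 0.00108). Of 13 genes of the NRF2 and metallothionein list 9 fell while Hmox1, Slc7a11, Gsr and G6pdx rose (median -0.64, camera adjusted p = 0.664). Hmox1, which degrades haem, rose by 2.20 ± 0.09 and the metal-binding Mt1 fell by 2.67 ± 0.16. Of 12 p53 targets 6 rose and Mdm2, Sesn1 and Plk3 fell (median 1.09, camera adjusted p = 0.0529). Of 12 hypoxia targets Hif1a, Adm, Ndrg1, P4ha1 and Ero1l rose and Vegfa, Bnip3 and Angptl4 fell (median 0.31, camera adjusted p = 0.121). Of 19 cell death genes 9 rose and Bid, Bbc3 and Tradd fell (median 0.27, camera adjusted p = 0.133). Mlkl, the executor of necroptosis, rose by 2.40 ± 0.16 and Mcl1, which protects from apoptosis, by 0.80 ± 0.07. Of 15 cell cycle genes Mki67, Top2a, Mcm5 and Mcm6 rose and Ccnd1, Ccne1 and Ccne2 fell (median 0.23, camera adjusted p = 0.666).

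In all, 27 of 38 lists were called after D-gal/LPS, 17 higher and 10 lower. With an estimated correlation 14 calls held. These were the lists of cytokines, chemokines, interferon-stimulated genes, NF-kB targets, immediate early genes, inflammasome, coagulation, neutrophils, monocytes and stellate cells among those higher. The lists of hepatocyte transcription factors, clock, stress response and gluconeogenesis held among those lower. By fry, which asks whether genes of a list move on balance one way, the largest adjusted p of a called list was 0.00219, for bile acid genes.

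WZB given before D-gal/LPS lowered interferon, cytokine and red blood cell transcripts and raised genes of hepatocyte metabolism, relative to D-gal/LPS alone. Of the 9 lists called higher only gluconeogenesis and glycogen held with an estimated correlation (adjusted p = 0.0356), and the others had an adjusted p = 0.0561 to 0.191 with it. Cyp4a14, a fatty acid hydroxylase under PPAR-alpha control, rose from 18.9 ± 5.38 to 123 ± 37.9 CPM (log2 fold change 2.70 ± 0.28, edgeR adjusted p = 0.000364, n = 3). Cyp2b10, a drug-metabolising enzyme under control of the receptor CAR, rose from 2.73 ± 1.09 to 17.5 ± 1.97 CPM (2.69 ± 0.28, edgeR adjusted p = 3.5e-05). Rsad2, the antiviral gene of viperin, fell from 335 ± 14.2 to 74.5 ± 13.4 CPM (-2.17 ± 0.13, edgeR adjusted p = 2.1e-06). Il6 fell by 2.08 ± 0.34, Ccl2 by 1.01 ± 0.09, Tnf by 0.94 ± 0.21 and Il1b by 0.80 ± 0.13 log2 units. Cyp7a1 had 35.0 ± 6.77 CPM without and 31.5 ± 3.77 CPM with WZB (edgeR adjusted p = 0.539). Alb rose by 0.38 ± 0.07 log2 units, a call that was lost with total-count scaling (adjusted p = 0.0754). Of 13583 genes, 1873 rose and 2001 fell with WZB (28.5% of all), 181 and 608 of them at least 2-fold. The groups' samples did not overlap for 45.3% of genes, against 10% by chance. The split of higher and lower genes depended on the scaling of the libraries. It was 2358 and 1643 with upper quartile factors, and 850 and 3290 with total-count scaling, which moved the median of all genes by -0.198. Fold changes with WZB are therefore relative to the TMM scaling.

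Among the other large rises with WZB were Scd1, which makes monounsaturated fatty acids (1.92 ± 0.24), Cyp4a10 (1.89 ± 0.24), Cyp2c55 (1.83 ± 0.15) and H2-Q1 (1.72 ± 0.22). Cyp4a10, Cyp4a14, Cyp2c55 and H2-Q1, and the globin genes named next, have close paralogs whose reads may have been shared. The handling of such reads is not given in the sources used here. Among the large falls were those of globin genes: Hbb-bs (-3.24 ± 0.50), Hbb-bt (-3.22 ± 0.25), Hba-a1 (-3.18 ± 0.26) and Hba-a2 (-3.18 ± 0.27). Saa1, an acute phase apolipoprotein, fell by 2.99 ± 0.83 (edgeR adjusted p = 0.0402).

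Inflammatory lists were lower with WZB. The count adjusted over the list alone is again given where it differs from the count over all genes, and exceptions named without a value were chosen after their values were seen. Of 20 interferon-stimulated genes 15 fell and none rose, and 17 fell adjusted over the list alone (median -1.04, camera adjusted p = 6.74e-21). Cmpk2 fell by 1.86 ± 0.10, Usp18, which curbs interferon signalling, by 1.5 ± 0.10 and Ifit3 by 1.41 ± 0.10. Of 14 cytokines 12 fell and none rose (median -1.5, camera adjusted p = 4.48e-14), with Csf3 at -2.24 ± 0.17. Of 18 chemokines 8 fell, and 10 adjusted over the list alone (median -0.73, camera adjusted p = 1.43e-09), among them Ccl3 (-1.58 ± 0.12). Of 11 genes of coagulation and fibrinolysis 7 fell and Tfpi2 rose (median -1.09, camera adjusted p = 4.39e-07), with Thbs1 at -2.10 ± 0.14 and Plaur at -1.35 ± 0.14. Of 19 NF-kB targets 15 fell, and 17 adjusted over the list alone (median -0.85, camera adjusted p = 5.05e-12, and adjusted p = 0.0561 with an estimated correlation). Of 19 immediate early genes 9 fell and none rose (median -0.47, camera adjusted p = 2.86e-05, and adjusted p = 0.0936 with an estimated correlation), with Fosl2 at -1.22 ± 0.10. Of 12 inflammasome genes Nlrp3, Casp1, Casp4, Gsdmd and Mefv fell, and 8 genes adjusted over the list alone (median -0.81, camera adjusted p = 0.000222, and adjusted p = 0.0532 with an estimated correlation). Of 19 cell death genes 11 fell, and 12 adjusted over the list alone, while 1 rose (median -0.57, camera adjusted p = 0.00143, and adjusted p = 0.0562 with an estimated correlation). Mlkl fell by 1.23 ± 0.15, and Cflar, an inhibitor of caspase 8, by 0.89 ± 0.08. Of 20 acute phase genes 9 fell, and 11 adjusted over the list alone, while Crp rose, a call lost with total-count scaling (adjusted p = 0.301) and DESeq2 (adjusted p = 0.0908) (median -0.42, camera adjusted p = 0.00172, and adjusted p = 0.393 with an estimated correlation). Lcn2, an iron-scavenging acute phase protein, fell from 228 ± 41.7 to 113 ± 10.4 CPM.

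Markers of several cell types were lower with WZB. Of 8 red blood cell transcripts 7 fell, and 8 adjusted over the list alone (median -2.72, camera adjusted p = 6.23e-16). Globin genes, members of that list that may share reads, took 0.0357 ± 0.0149% of reads with WZB, against 0.3805 ± 0.0546% without. Of 14 stellate cell and fibroblast markers 8 fell, and 11 adjusted over the list alone, while Lrat and Des rose (median -0.71, camera adjusted p = 3.04e-05). Reln fell by 1.2 ± 0.10 and Dcn by 0.82 ± 0.08. Of 13 macrophage markers 12 fell (median -0.92, camera adjusted p = 7.07e-09, and adjusted p = 0.0837 with an estimated correlation), with the complement gene C1qb at -1.11 ± 0.14. Of 12 monocyte markers 8 fell (median -0.99, camera adjusted p = 7.69e-07, and adjusted p = 0.0561 with an estimated correlation), with Cd14 at -1 ± 0.13. Of 13 neutrophil markers 8 fell, and 9 adjusted over the list alone (median -0.86, camera adjusted p = 9.57e-06, and adjusted p = 0.0554 with an estimated correlation). Hdc, which makes histamine, fell by 1.2 ± 0.13, while S100a9 had 103 ± 18.2 CPM without and 89.7 ± 5.23 CPM with WZB (edgeR adjusted p = 0.221). With total-count scaling S100a9 was called lower (log2 fold change -0.41, adjusted p = 0.0213). Of 12 Kupffer cell markers 7 fell, and 8 adjusted over the list alone, while Slc40a1 rose, a call lost with total-count scaling (adjusted p = 0.101) (median -1.06, camera adjusted p = 7.88e-05, and adjusted p = 0.102 with an estimated correlation). Clec4f fell by 1.32 ± 0.12 and Timd4, a receptor for dying cells, by 1.51 ± 0.24. Of 14 sinusoidal endothelial markers 6 fell and Kdr rose (median -0.37, camera adjusted p = 0.00249, and adjusted p = 0.257 with an estimated correlation), with Cdh5 at -1.30 ± 0.11. Of 13 T, NK and B cell markers Nkg7, Gzma, Gzmb and Prf1 fell, all genes of killer cells (median -0.31, camera adjusted p = 0.0184, and adjusted p = 0.191 with an estimated correlation). The call of that list was also lost with total-count scaling (camera adjusted p = 0.062). None of 8 cholangiocyte markers was called (median -0.05, camera adjusted p = 0.743).

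**Figure D3:**
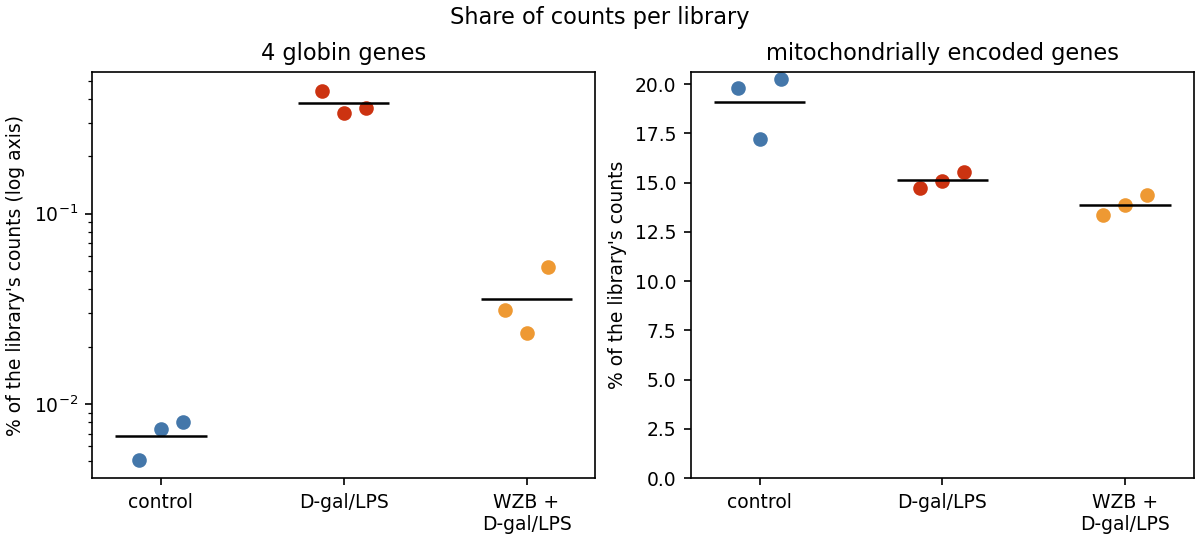
Share of reads on globin genes, on a log axis, and on mitochondrial genes, on a linear axis, in each library. Points are libraries and lines are the means of 3.

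Genes of hepatocyte metabolism were higher with WZB, in livers where the macrophage marker median stood at -0.92 and the red blood cell median at -2.72. Of 14 genes of gluconeogenesis and glycogen 7 rose and none fell, and 9 rose adjusted over the list alone (median 0.52, camera adjusted p = 0.000232). Slc37a4, which carries glucose 6-phosphate into the ER, rose by 0.77 ± 0.11, while G6pc had 37.5 ± 4.54 CPM without and 38.6 ± 1.41 CPM with WZB (edgeR adjusted p = 0.831). Of 18 xenobiotic genes 14 rose and none fell, and 15 adjusted over the list alone (median 0.76, camera adjusted p = 4.22e-11, and adjusted p = 0.105 with an estimated correlation). Cyp2e1, which oxidises ethanol and paracetamol, rose from 4432 ± 632 to 8937 ± 535 CPM. Of 19 genes of fatty acid oxidation and ketogenesis 17 rose and none fell (median 0.52, camera adjusted p = 5.64e-11, and adjusted p = 0.0561 with an estimated correlation). Ehhadh, a peroxisomal enzyme, rose by 0.95 ± 0.09, and Acadl, an acyl-CoA dehydrogenase, by 0.67 ± 0.08. The call of Cpt1a, also counted there, was lost with total-count scaling (log2 fold change 0.03, adjusted p = 0.79). All 18 genes of oxidative phosphorylation rose (median 0.47, camera adjusted p = 1.58e-08, and adjusted p = 0.147 with an estimated correlation). Ndufa9 of complex I rose by 0.62 ± 0.09 and Uqcrfs1 of complex III by 0.52 ± 0.07. Of 16 genes of the urea cycle and amino acid catabolism 13 rose while Nags and Hal fell (median 0.56, camera adjusted p = 2.83e-06, and adjusted p = 0.171 with an estimated correlation). Tdo2, which opens tryptophan breakdown, rose by 0.85 ± 0.10. Of 19 secreted hepatocyte proteins 13 rose and none fell (median 0.39, camera adjusted p = 1.34e-05, and adjusted p = 0.13 with an estimated correlation), with Ttr, a carrier of thyroid hormone, at 0.77 ± 0.09. Of 13 lipogenesis genes 7 rose, and 8 adjusted over the list alone, while Srebf1 fell (median 0.43, camera adjusted p = 4.35e-05, and adjusted p = 0.191 with an estimated correlation). Me1, a source of NADPH, rose by 1.40 ± 0.10 and Thrsp by 0.99 ± 0.10. Of 14 bile acid genes 6 rose and none fell, and 7 adjusted over the list alone (median 0.55, camera adjusted p = 4.8e-05, and adjusted p = 0.171 with an estimated correlation). The uptake carriers Slco1b2 (0.87 ± 0.11) and Slc10a1 (0.72 ± 0.09) were among them. Of 14 genes of galactose and uridine metabolism 6 rose while Cad and Upp1 fell (median 0.35, camera adjusted p = 0.0158, and adjusted p = 0.102 with an estimated correlation), with Upp2, the liver uridine phosphorylase, at 0.92 ± 0.10.

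Other lists were not called with WZB. Of 12 hepatocyte transcription factors Hnf4a rose and Cebpb fell, and only Hnf4a passed adjusted over the list alone (median -0.13, camera adjusted p = 0.674). The call of Cebpb was lost with upper quartile factors (adjusted p = 0.064) and in 7 of the 9 fits that left out a library. Cebpa had 21.9 ± 4.25 CPM without and 22.4 ± 2.43 CPM with WZB. Of 17 glycolysis genes 9 fell, Hk2 by 1.29 ± 0.15, Hk1 by 1.30 ± 0.15 and Pkm by 0.91 ± 0.11. In that list Pgk1, Pgam1, Eno1 and Pdk1 rose, and 5 genes adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.0592). With total-count scaling that median was -0.49, and those of the transcription factor (-0.33), clock (-0.42) and p53 (-0.32) lists also moved down. Pdk1, which restrains pyruvate dehydrogenase, rose by 1.19 ± 0.11. Of 10 mitochondrially encoded genes mt-Nd1 and mt-Nd2 rose (median 0.17, camera adjusted p = 0.0697), and with total-count scaling the list median was -0.03 and the call of mt-Nd2 was lost (adjusted p = 0.423). Mitochondrial genes took 13.9 ± 0.503% of reads with WZB. Of 12 hypoxia targets Hif1a, Adm, Ndrg1 and P4ha1 fell and Bnip3 rose (median -0.39, camera adjusted p = 0.174). Of 15 cell cycle genes Mki67, Top2a, Ccnd1 and Mcm6 fell and Ccne2 rose (median -0.39, camera adjusted p = 0.195). Of 16 cholesterol genes 4 rose, Cyp51, Nsdhl and Insig1 among them, and 1 fell (median 0.13, camera adjusted p = 0.198). With total-count scaling that median was -0.07, and the calls of Cyp51 (adjusted p = 0.332) and Nsdhl (adjusted p = 0.143) were lost, that of Cyp51 also with DESeq2 (adjusted p = 0.0678). Of 14 clock genes Per2 and Per3 fell and Nr1d1 rose (median -0.23, camera adjusted p = 0.416), and the call of Nr1d1 was lost with total-count scaling (adjusted p = 0.0673). Of 12 p53 targets Cdkn1a, Mdm2 and Plk2 fell and Ccng1 rose, and 2 rose adjusted over the list alone (median -0.11, camera adjusted p = 0.665). Of 13 genes of the NRF2 and metallothionein list Nqo1, Gclm and Aox1 rose, and 4 adjusted over the list alone, while Hmox1, Txnrd1 and Slc7a11 fell (median 0.12, camera adjusted p = 0.737). With total-count scaling the median of that list was -0.08. Of 15 genes of the integrated stress response and ER stress Ddit3, Herpud1 and Vldlr rose, and Atf4, Chac1, Hspa5 and Xbp1 fell (median -0.12, camera adjusted p = 0.952). The call of Herpud1 was lost with total-count scaling (adjusted p = 0.0825).

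With WZB 26 of 38 lists were called, 9 higher and 17 lower. With an estimated correlation 7 held: interferon-stimulated genes, red blood cell transcripts, cytokines, chemokines, coagulation, stellate cells and gluconeogenesis. By fry the largest adjusted p of a called list was 0.0163, for acute phase genes. With total-count scaling several medians moved by over 1.5 times. They were then 0.19 for secreted proteins, 0.27 for oxidative phosphorylation, 0.32 for fatty acid oxidation, 0.33 for gluconeogenesis, 0.23 for lipogenesis, 0.35 for bile acid genes, 0.36 for the urea cycle and 0.15 for galactose and uridine metabolism. Sinusoidal endothelial markers (-0.56) and T, NK and B cell markers (-0.50) moved further down. The call of Saa1 was lost in 8 of the 9 fits that left out a library.

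Many genes that changed with D-gal/LPS moved the opposite way with WZB. Serpina3f, a protease inhibitor gene, rose by 6.69 ± 0.12 log2 units with injury and fell by 1.40 ± 0.09 with WZB. Rsad2 rose by 6.00 ± 0.16 and fell by 2.17 ± 0.13, and Cyr61, a matrix signal of injured tissue, rose by 4.95 ± 0.12 and fell by 1.55 ± 0.11. Cmpk2 rose by 4.50 ± 0.12 and fell by 1.86 ± 0.10, Itpkb, an inositol phosphate kinase, rose by 4.31 ± 0.14 and fell by 1.62 ± 0.12, and Ifit3 rose by 4.01 ± 0.11 and fell by 1.41 ± 0.10. Of 7931 injury genes 1913 (24.1%) moved back and 726 moved further. Of the 3957 genes that rose with injury, 1333 fell with WZB, where independent lists would give 583. Of these 1333 genes, 1009 were still above control with WZB, 299 were not called against control and 25 were below it. Of the 3974 genes that fell with injury, 580 rose with WZB, where independent lists would give 548. Of these, 145 were still below control, 378 were not called and 57 were above it. A further 426 genes rose in both comparisons and 300 fell in both, against 546 and 585 for independent lists. The 2 comparisons share the D-gal/LPS libraries, which alone makes opposite signs common. In 20 simulations of unchanged groups with shared libraries the correlation of fold changes averaged -0.489 (range -0.548 to -0.431). The observed value was -0.524. Opposite signs were found for 59.9% of genes, against 66.6% in the simulations. Sharing a group sets both simulated values in advance, so neither can tell whether sharing explains the opposite movement. The covariance was -0.505 against -0.048 in the simulations, so sharing with the simulated spread gave only a small part of it. Calls in opposite directions numbered 1913 against a mean of 0.1, but unchanged groups have few calls by construction. In a test added after the data were seen, 1 D-gal/LPS library was used in one comparison and the other 2 in the other, in each of 6 ways. With no library shared, the correlation was -0.481 to -0.405 and 821 to 1420 genes moved back. Of these, 619 to 1112 rose with injury and were lower with WZB, where independent lists would give 200 to 425. The genes that fell and were then higher did not exceed the number for independent lists in every split. These fits have fewer libraries in each comparison, and a single library was taken to vary as the others do.

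**Figure D4:**
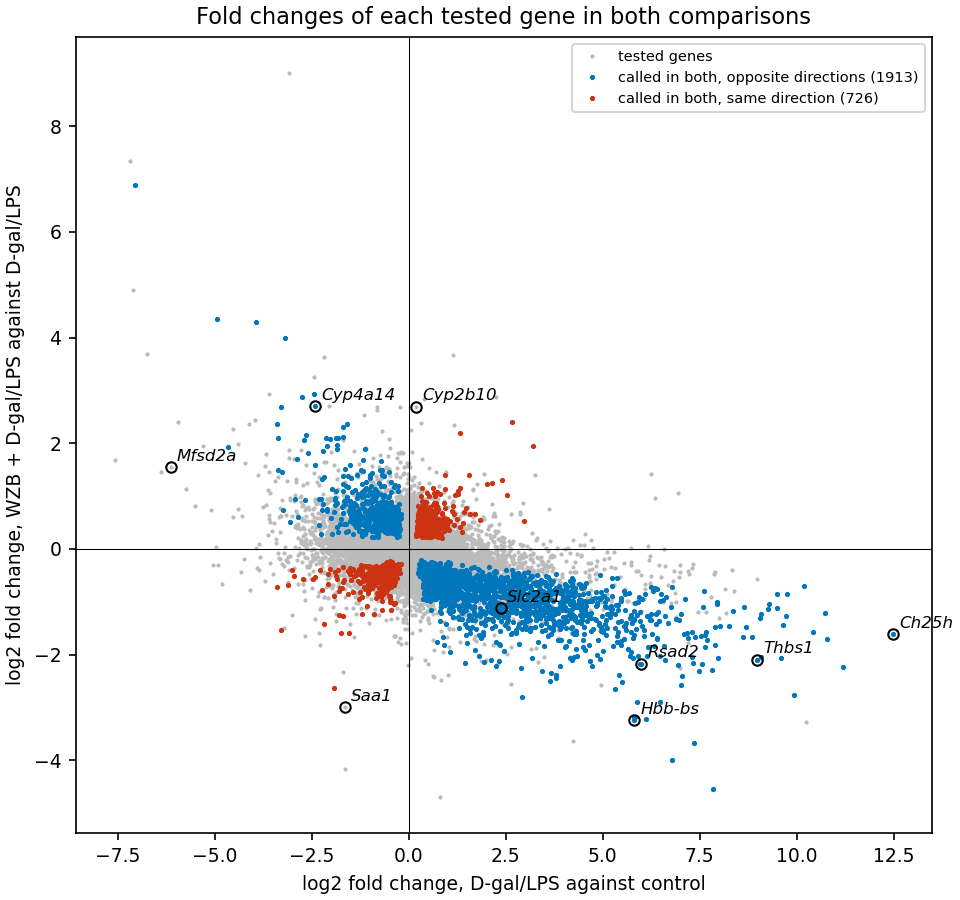
Log2 fold change with D-gal/LPS against control (horizontal) and with WZB against D-gal/LPS alone (vertical) for each tested gene. Blue points are the 1913 genes called in opposite directions and red points the 726 called in the same direction.

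Livers given WZB and D-gal/LPS still differed widely from control livers. Ccl2 was at 81.6 ± 8.23 CPM against 0.652 ± 0.0426 in controls (log2 fold change 6.95 ± 0.14, edgeR adjusted p = 1.76e-12, n = 3). S100a9 was higher by 5.99 ± 0.16 and Slc2a1 by 1.25 ± 0.15. Cebpa was lower by a log2 fold change of -2.89 ± 0.14 and Cyp7a1 by -2.83 ± 0.17. Upp2 (0.02 ± 0.10, edgeR adjusted p = 0.874) and Clec4f (0.05 ± 0.12, edgeR adjusted p = 0.732) did not pass the test against control. Of 13583 genes 4430 were higher and 3806 lower than in control livers (60.6% of all), 2290 and 1861 of them at least 2-fold. The split was 3248 and 5061 with total-count scaling, which moved the median of all genes by -0.254. The groups did not overlap for 65.9% of genes, against 10% by chance. Of 38 lists 24 were called, 19 higher and 5 lower, and 11 of them held with an estimated correlation. With total-count scaling 22 held, and the lists of xenobiotic genes (median 0.43, camera adjusted p = 0.051) and secreted hepatocyte proteins (median 0.38, camera adjusted p = 0.0594) lost their calls. All 13 neutrophil markers were higher (median 5.60, or 5.42 at the bound, camera adjusted p = 8.12e-27), as were all 12 monocyte markers (median 3.99, camera adjusted p = 1.08e-17). Cytokines (median 3.48, 13 of 14 higher, camera adjusted p = 3.08e-11) and chemokines (median 3.99, or 3.72 at the bound, 16 of 18 higher, camera adjusted p = 1.09e-19) were also above control. Of 20 interferon-stimulated genes 16 were higher, and 17 adjusted over the list alone, while Stat2 was lower (median 2.41, camera adjusted p = 4.4e-15). All 14 stellate cell and fibroblast markers were higher (median 2.09, camera adjusted p = 1.23e-11). Hepatocyte transcription factors stayed low, with 10 of 12 below control (median -1.84, camera adjusted p = 5.77e-09). Oxidative phosphorylation genes stood above control, with 17 of 18 higher (median 0.66, or 0.41 with total-count scaling, camera adjusted p = 0.00061, and adjusted p = 0.406 with an estimated correlation). Xenobiotic genes were also above control, 11 of 18 higher and Por and Nr1i3 lower (median 0.69, camera adjusted p = 0.0371, and adjusted p = 0.597 with an estimated correlation). Of 12 Kupffer cell markers Timd4, Marco, Folr2, C6 and Clec1b were higher and Cd163, Slc40a1 and Kcna2 lower (median 0.27, or 0.02 with total-count scaling, camera adjusted p = 0.71).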

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

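Total-count scaling, removal of mitochondrial and globin genes, limma on log2(FPKM + 1), and a split of the D-gal/LPS libraries between the comparisons were chosen only after the results had been seen, and the other alternatives were fixed before. No named gene or list that passed its test passed it in the other direction under any alternative that was run. With D-gal/LPS against control, leaving out each library in turn gave 3679 to 4045 higher and 3511 to 4039 lower genes. With WZB against D-gal/LPS alone the ranges were 1232 to 1947 higher and 1410 to 2315 lower, and with WZB and D-gal/LPS against control 4045 to 4385 higher and 3526 to 4167 lower. Between 1374 and 1969 genes moved back and between 426 and 686 moved further. The lowest count of genes higher with WZB, 1232, came without D-gal/LPS replicate 2. In the same fit 2315 genes were lower, against 2001 with all libraries, so the balance of higher and lower genes shifted with this library. Without D-gal/LPS replicates 1 and 3, 467 and 426 genes moved further. These fits have fewer samples. With a log2 fold change of at least 1 required, which can only lower counts, 2454 genes were higher and 1731 lower with D-gal/LPS, 181 higher and 608 lower with WZB, and 2290 higher and 1861 lower with both against control. Then 597 genes moved back and 21 moved further. With D-gal/LPS replicate 1, 2 or 3 alone against control and the other 2 against WZB, 1365, 1420 and 1274 genes moved back and 296, 643 and 294 moved further. With the replicate alone against WZB and the other 2 against control, 1164, 821 and 915 moved back and 469, 152 and 243 moved further. Each comparison in these splits has fewer libraries. Total-count scaling gave 850 higher and 3290 lower genes with WZB, holding 850 and 2001 of those called with TMM factors. It leaves out the factors that raise all genes of the WZB libraries, which lay between 0.872 and 0.924, against 1.003 to 1.05 after D-gal/LPS and 1.06 to 1.101 in controls. limma on log2(FPKM + 1), which also uses no such factors, gave 913 higher and 3384 lower genes with WZB, 896 and 1983 of them shared. The call of Saa1 with WZB was lost without 8 of the 9 libraries and with a block on the replicate number (adjusted p = 0.0917), and that of Slc2a2 without 5 libraries. With WZB the calls of Crp (5 libraries), Xbp1 and Cyp51 (4 each), Nr1d1 and mt-Nd2 (3 each), Herpud1, Per2, Slc7a11 and Srebf1 (2 each) and Cdkn1a, Gclm, Hspa5, Nsdhl, Prf1 and Slc40a1 (1 each) were also lost without single libraries, as was that of Otc with D-gal/LPS (4). Genes named outside the rule were not followed through the alternatives. The bile acid list of D-gal/LPS livers lost its call without 4 libraries (camera adjusted p = 0.0518 to 0.0652) and when only 2 groups were fitted (0.109). The p53 list of these livers was called without 5 libraries (camera adjusted p = 0.0322 to 0.0483). The glycolysis list was called lower with WZB under DESeq2 size factors (camera adjusted p = 0.0407), total-count scaling (0.016), a fit of 2 groups (0.0383), and without 5 libraries (0.0256 to 0.038). The mitochondrial list was called higher with WZB without WZB replicate 1 (camera adjusted p = 0.0407) or 2 (0.0391), and the cholesterol list without D-gal/LPS replicate 1 (0.00322). The call of the T, NK and B cell list with WZB was lost without WZB replicate 2 (camera adjusted p = 0.05). A block on the replicate number gave 3889 and 3867 genes with D-gal/LPS and 1779 and 1879 with WZB. It changed no call of a list, and lost Nqo1 with D-gal/LPS (adjusted p = 0.0665) and Cpt1a (0.0502) and Por (0.0812) with WZB. These calls were also lost with DESeq2 (adjusted p = 0.0653 for Nqo1, 0.124 for Cpt1a and 0.0794 for Por). Several fits without 1 library lost them too (Nqo1 0.0515 to 0.193, Cpt1a 0.0552 to 0.16, Por 0.0764 to 0.155). Such fits also lost the call of Cebpb with D-gal/LPS (0.0501 to 0.0941). Residual correlations of libraries with the same number in different groups averaged -0.02 over 9 pairs (-0.067 to 0.042), and those of the other 18 pairs lay between -0.04 and 0.082. The cause of changes with other alternatives was not tested. In the simulations small changes were often missed. With this depth, this spread and 3 libraries a group, 16.4% of simulated 1.5-fold changes were called with D-gal/LPS and 20.9% with WZB. The part of depth in this was not separated. Few simulated genes were changed, which made the adjusted threshold stricter than in the real comparisons, so these values do not give the share missed there.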

Other observations

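The tests on differences of list medians and on summed red cell counts were chosen only after the results they weigh had been seen, and the spread that each of the other tests had to clear was also set after its first values were known. The rules for the hepatocyte share and for the summed counts were also made stricter after their values were known. The intervals of list medians below come from resampling the genes of a list, not the libraries. They treat its genes as independent, so they may be too narrow and leave out the spread between samples. A set of 1235 genes was called with WZB but not with D-gal/LPS, of which 867 rose and 368 fell with WZB under TMM scaling. That split depends on the scaling, since total-count scaling called only 850 genes higher and 3290 lower with WZB in all. A gene not called with D-gal/LPS may still have changed, since the test does not call every change. Cyp2b10 had 2.38 ± 0.708 CPM in control livers, 2.73 ± 1.09 CPM after D-gal/LPS and 17.5 ± 1.97 CPM with WZB. Among falls, Lcn2 had 230 ± 14.2 CPM in controls, 228 ± 41.7 CPM after D-gal/LPS and 113 ± 10.4 CPM with WZB. Conversely, 5292 genes that changed with D-gal/LPS were not called with WZB. Among them was Gadd45b, a stress-induced gene, with 61.5 ± 8.37 CPM without and 64.7 ± 7.81 CPM with WZB (edgeR adjusted p = 0.755).

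Hepatocyte transcription factors fell with D-gal/LPS while secreted proteins did not, and their list medians differed by -1.79 (95% bootstrap interval -2.56 to -1.06, 12 and 19 genes). This difference is the pattern itself and no new test, but dilution of hepatocyte RNA by other cells would lower both lists alike, so the value argues against dilution as the whole cause. After removal of the trend on GC content and transcript length the difference was -1.82 (-2.60 to -0.95), which argues against those as well. As a class of short-lived transcripts chosen by name, 280 zinc finger genes had a median log2 fold change of -0.79 (-0.91 to -0.63), with 157 lower and 18 higher, and -0.84 with total-count scaling, and 2 of them had been seen before the test was written. A loss of short-lived transcripts may be a part of the fall. These values cannot tell lowered synthesis from faster decay, and both remain open without half-lives measured in these livers.

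Xenobiotic genes were higher with WZB (camera adjusted p = 4.22e-11, and adjusted p = 0.105 with an estimated correlation), and 21 measured genes of the response to the receptors CAR and PXR had a median of 0.93 against control livers (0.68 to 1.32), with 17 higher and 1 lower. The median was 0.68 with total-count scaling and 0.95 with upper quartile factors. With D-gal/LPS alone the list median was -0.04 against control, so the list had not fallen as a whole. This argues against a mere return to the control level. Given that, the height above control follows from the rise with WZB and is no separate test of induction. Against control, secreted hepatocyte proteins (0.64) and oxidative phosphorylation genes (0.66) also stood higher, while gluconeogenesis (-0.29) and lipogenesis (-0.02) genes did not. Induction of the CAR and PXR genes is therefore not singled out. Their list shares 7 genes with the lists fixed before, and some members had been seen higher with WZB beforehand. The xenobiotic list exceeded the hepatocyte transcription factor list by 0.89 with WZB (0.65 to 1.26, 18 and 12 genes), but the urea cycle list by only 0.20 (-0.05 to 0.44), fatty acid oxidation by 0.24 (-0.04 to 0.47) and secreted proteins by 0.37 (0.16 to 0.61), so a larger hepatocyte share stays open. Without a group given WZB alone, an effect of WZB itself and an effect that needs injury cannot be told apart, and reads shared between Cyp2b, Cyp2c and Gstm paralogs remain possible.

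Red blood cell transcripts were higher with D-gal/LPS (adjusted p = 0.0586 with an estimated correlation) and lower with WZB (adjusted p = 0.0356 with an estimated correlation). Of 10 late red cell genes listed beforehand Ahsp was not found in the table and only Sptb (-0.26) and Slc25a37 (-0.47) could be tested. Their median of -0.36 lies where the written prediction counts against red blood cells in the tissue, but 2 genes were held too few to decide. The 7 genes too low to test had 10, 186 and 45 counts in control, D-gal/LPS and WZB livers, a ratio of 18.9 over control (10 to 40, from counting noise only) and 4.19 over WZB, but their counts had been seen before, all 10 control counts lay in control replicate 2, and Ermap went from 27 to 32 counts with WZB. Of 8 precursor genes 5 could be tested (median 2.13, -2.18 to 3.17, and -0.31 with WZB). With D-gal/LPS, Kit, Tal1 and Nfe2, also genes of other blood cells, rose, and Car1 rose by 0.67 ± 0.21. Klf1, an erythroid factor, fell by 2.18 ± 0.44. Among the genes too low to test, Epor went from 29 to 3 counts, Gata1 from 0 to 12 and Gfi1b from 0 to 2. Red blood cells in the tissue and formation of red cells in the liver both stay open.

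To ask whether any grouping of libraries would give such counts, each set of 6 libraries was split in every way. There are 10 splits into 3 and 3, which cannot give a share under 0.05. Each split other than the real one also mixes the groups, so a real difference enters the spread and leaves few calls. The counts of those splits are therefore no rate of false calls and do not decide the question. The real splits called 7931, 3874 and 8236 genes for D-gal/LPS against control, WZB against D-gal/LPS alone, and both against control, and the highest other split called 1, 1 and 1.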
